A study of Mus musculus with 8 samples.

How the data were processed

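MicroRNA (miRNA) levels were measured in kidneys of ICR mice, an outbred laboratory strain, 7 days after ligation of one ureter, a surgical model of urinary obstruction. Per the labels, 4 arrays held RNA from contralateral kidneys without obstruction and 4 held RNA from obstructed kidneys. Total RNA was extracted with Trizol and a miRNA column kit, and 100 ng was labelled with Cy3, per the labels' protocols. Each sample was hybridised to its own Agilent mouse miRNA array with 1 colour. The file headers place all 8 arrays on 1 slide with 1 scan, so neither slide nor scan could differ between the groups. Slide row 1 held kidneys 1 and 2 of both groups and slide row 2 held kidneys 3 and 4 of both.

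The deposited values were spot intensities from Agilent Feature Extraction, version 10.1.1 per the submitters' processing notes and 10.7.3.1 per the file headers. The software had subtracted local background, removed spatial trends and marked outlier spots, per the file headers, and no scaling between arrays had been applied. The intensity values in the authors' series matrix equalled the processed spot signals of the scanner files exactly. Their direction and scale were therefore known, and they carried no centring. Each array had 13715 spots, of which 13000 were not controls. Between 2.34% and 3.52% of those were marked as outliers and left out, and no spot was saturated. The other deposited values used for the main results were marks of 0 or 1 per spot for outliers, saturation and signal well above background, per the file headers. Alternatives also used the median spot and background signals and the summed gene signal.

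Spots of a probe were averaged, which left 1759 probes for 611 mouse miRNAs. Each array was divided by its 75th percentile over the 371 probes well above background on all 8 arrays. Scaled signals of the probes of a miRNA were summed, a common floor of 0.0213 was set, and log2 was taken. The floor was the median over arrays of the 1st percentile of scaled signals of probes above background. A probe counted as above background on an array when over 50% of its spots carried that mark, and a miRNA when at least 1 of its probes did. Mouse miRNAs above background on all 4 arrays of at least 1 group were tested, which left 222 miRNAs. Values at the floor understate the change of dim miRNAs.

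This scaling assumes that the 75th percentile of the 371 probes above background on all arrays is the same in both groups. A fold change is therefore a change relative to the bright miRNAs of the same array, and not a change in the number of molecules per cell. Array signal and the number of detected miRNAs limit the precision, and the 8 arrays limit it further. Nothing in the labels says whether kidneys with the same number came from the same mouse. The labels call the kidneys of a group separate samples without stating that they came from separate mice. The p-values therefore measure only the spread between these samples.

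Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 222 miRNAs, and called at an adjusted p under 0.05. Fixed miRNA lists with at least 3 tested members (9 of 15) were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's members move one way on balance, stood beside it. List p-values were adjusted over the 9 lists. Counts of list members that rose or fell are counts of called members. The lists were the fibrosis-associated group of miR-21, miR-214 and miR-199, the miR-29, miR-200, miR-30 and let-7 families, the family of miR-34 and miR-449, the miR-17-92 clusters, a kidney tubule group, the Dlk1-Dio3 cluster, and markers of leukocytes, erythroid cells, striated muscle, smooth muscle, endothelium, and brain, liver and pancreas. Array signal was compared with exact permutation tests over all 70 assignments, which cannot give a p below 0.0286. Extraction and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

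The miRNAs named were chosen by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called miRNAs whose obstructed arrays all lay beyond all contralateral arrays. It always took miR-21, miR-34a, miR-34c, miR-29c, miR-192, miR-200b and miR-210, and up to 4 members of each list, called members first and then by mean signal. Only 3 rises met the first part, and the rule named 55 miRNAs in all. Names are those of the array design and can be old, and an asterisk marks the less abundant strand of a precursor in that naming. No genome coordinates were used here.

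The fitting steps were tested on simulated data for the comparison of obstructed with contralateral kidneys, with the means and residual spread of the 222 miRNAs, independent noise and 20 runs. With 4 against 4 arrays, 27.3% of miRNAs changed by 0.5 on the log2 scale were called, 66.5% of those changed by 1 and 90.5% of those changed by 2. Of all calls, 2.38% were of unchanged miRNAs, and no miRNA was called in data without changes. A list shifted by 1 was called in 75% of runs, and 2 list calls were made over the 20 runs without changes. The simulated noise was independent between miRNAs and had the same spread in both groups. In the real arrays the estimated correlation within a list reached 0.94. These rates therefore need not hold for the real arrays.

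The alternatives covered other scalings (75th percentile over all probes, median, quantile, none), normexp background correction, other probe summaries (brightest probe, mean of log2 probes, the deposited summed gene signal), the authors' series matrix values, other filters and floors, eBayes with trend or robust, array weights, the replicate number or slide row as a block, each slide row alone, and each array left out in turn. Normexp was run on the median spot signal with an offset of 50, because the scanner files analysed here hold no mean signal column. Further alternatives without obstructed kidney 2 were added after the data were examined. Probes for 39 viral miRNA names stayed out of the comparison.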

Results

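The arrays measured 611 mouse miRNAs in 4 contralateral and 4 obstructed kidneys, taken 7 days after ligation of one ureter. Between 228 and 240 miRNAs were well above background on the contralateral arrays. On the obstructed arrays the numbers were 250, 243, 288 and 310 for kidneys 1 to 4. The comparison of obstructed with contralateral kidneys asks which miRNAs differ in a kidney whose outflow is blocked.

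Signal before scaling was higher on most obstructed arrays. The 75th percentile signal was 513, 417, 552 and 582 on the contralateral arrays and 689, 514, 1403 and 1595 on the obstructed arrays. The log2 difference between group means was 0.88 (SD 0.79 in obstructed and 0.21 in contralateral kidneys, n = 4 each), with an exact permutation p of 0.0857, two-sided. When obstructed kidney 2 was left out the difference was 1.17, with an exact permutation p of 0.0286, the smallest that 3 against 4 arrays allow. Obstructed kidney 2 was the dimmest obstructed array and was picked on its values, so leaving it out raises the difference by its own nature. This was the largest difference when each array was left out in turn. The number of detected miRNAs was 273 ± 31.7 in obstructed and 232.5 ± 5.74 in contralateral kidneys (SD, n = 4 each), with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays allow. Within slide row 1 the obstructed arrays exceeded the contralateral arrays by 0.36 in log2 signal and 12.5 miRNAs, and within slide row 2 by 1.40 and 68 (2 against 2 arrays each, not tested).

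**Figure D1:**
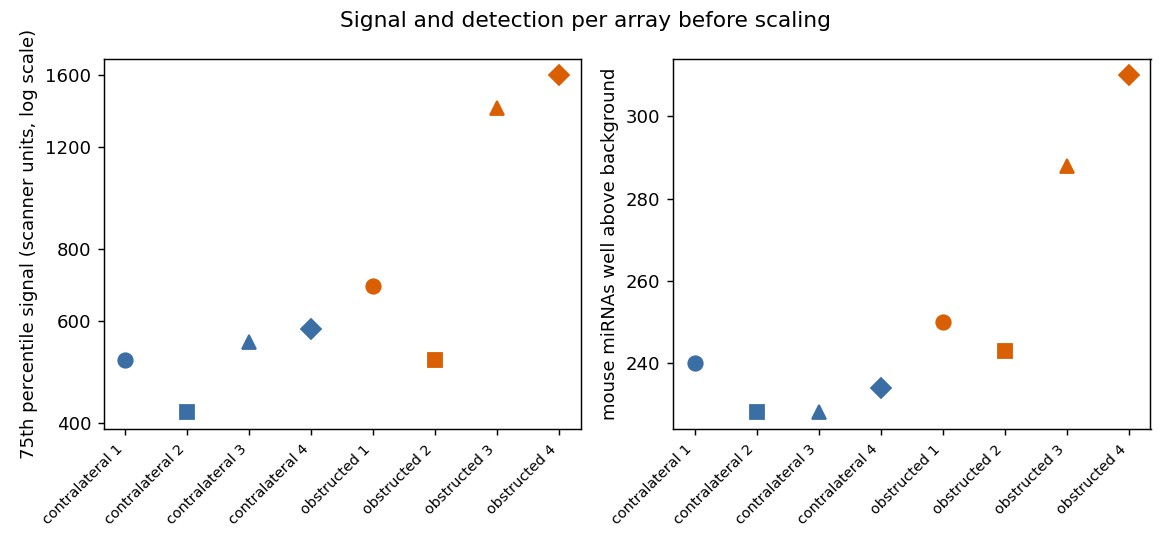
Signal before scaling (left, 75th percentile in scanner units on a log axis) and mouse miRNAs well above background (right) for each of the 8 arrays. Each point is one array, blue for contralateral and orange for obstructed kidneys; obstructed kidneys 3 and 4 reach 1403 and 1595, while obstructed kidney 2 at 514 lies among the contralateral arrays.

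Relative to the bright miRNAs of each array, miR-192 and miR-194, which are abundant in kidney tubule epithelium, fell in obstructed kidneys. The log2 change of miR-192 was -1.27 ± 0.26 (SE, n = 4 each), a level 2.41-fold lower, and that of miR-194 was -1.31 ± 0.18, or 2.48-fold lower. miR-29c, of a family known to target collagen messenger RNAs, fell by 1.09 on the log2 scale (SE 0.17), and miR-30e, of a family abundant in kidney epithelium and podocytes, by 1.36 (SE 0.35). Only 3 miRNAs were called higher, namely miR-135a*, miR-877 and miR-680. Others lay above 0 without being called.

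Of the 222 miRNAs tested, 33 differed between the groups (limma, Benjamini-Hochberg adjusted p under 0.05), 3 higher and 30 lower in obstructed kidneys. A change of at least 2-fold was found for 15, with 3 higher and 12 lower. At an unadjusted p under 0.05 there were 81. The 4 obstructed arrays lay wholly beyond the 4 contralateral arrays for 51 miRNAs, or 23.0% of those tested. Chance gives 2.86% for a single miRNA. The miRNAs share the same arrays and are not independent, so these shares alone do not exclude chance. Of the 51 miRNAs, 47 were lower and 4 higher, and 32 of the 33 called miRNAs were among them. The exception was miR-805, with a log2 change of -1.98 ± 0.51 (SE, n = 4 each), whose groups overlapped and which was chosen after its values were seen, outside the naming rule.

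The calls depended on single arrays and on the scaling. Leaving out contralateral kidney 1, 3 or 4 or obstructed kidney 1 or 3 left 0 calls (limma, smallest adjusted p from 0.0520 to 0.0678, with 54 to 67 miRNAs at an unadjusted p under 0.05). Without contralateral kidney 2 there were 20 and without obstructed kidney 4 there were 14. Scaling over all mouse probes gave 0 calls (56 at an unadjusted p under 0.05), and the split was 1 higher and 2 lower with quantile normalization, 2 higher and 1 lower with the summed gene signal, and 3 higher and 0 lower without scaling (64 at an unadjusted p under 0.05). The median log2 change of all tested miRNAs, -0.14, moved by 0.88 without scaling, by 0.87 with the unscaled series matrix, by -0.48 with normexp and by 0.12 with the summed gene signal. Within slide row 1 limma called 0 miRNAs (1 at an unadjusted p under 0.05) and within slide row 2 it called 69, 20 higher and 49 lower, from 2 against 2 arrays each. The medians of all 9 tested lists had the same sign in both slide rows. In slide row 1 this does not mean that obstructed kidneys 1 and 2 moved alike. Their list means were 2.10 and -0.46 for leukocyte markers and 0.82 and -0.33 for the miR-17-92 clusters. For the group of miR-21, miR-214 and miR-199 they were 1.91 and -0.54.

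The array of obstructed kidney 2 stood apart from the other obstructed arrays. Across miRNAs, which are not independent replicates, its mean correlation was 0.964 with the contralateral arrays and 0.887 with the other obstructed arrays, and limma's array weights gave it 0.114. Without it, 113 miRNAs differed (limma, adjusted p under 0.05), 46 higher and 67 lower, and 55 by at least 2-fold. All 33 calls of the comparison with 8 arrays were among them, in the same direction. Dropping the array that lay nearest to the other group raises the number of calls by its own nature, so values without obstructed kidney 2 stand beside those of all 8 arrays and do not replace them. Without scaling, that fit gave 113 higher and 2 lower miRNAs, since the median of all tested miRNAs then moved by 1.17 on the log2 scale, and with normexp it gave 7 higher and 26 lower.

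The 12 largest falls among called miRNAs whose groups did not overlap included both strands of the miR-455 precursor. miR-455* changed by -1.51 ± 0.29 and miR-455 by -1.32 ± 0.34 on the log2 scale (SE, n = 4 each), with limma adjusted p-values of 0.0172 and 0.0335. The probes of miR-455* gave between -1.27 and -0.035. miR-365 changed by -1.23 ± 0.24, miR-185 by -1.16 ± 0.25, miR-101a by -1.13 ± 0.20 and miR-193* by -1.11 ± 0.29. The fall of miR-107 was -0.96 ± 0.18. The strands miR-29c* and miR-29c changed by -1.10 ± 0.25 and -1.09 ± 0.17. Without scaling, the 12 falls were between -0.63 (miR-455*) and -0.078 (miR-107) and none was called (limma adjusted p from 0.389 to 0.926), so their calls hold only relative to the bright miRNAs.

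The largest rise among called miRNAs, miR-135a*, was 1.80 ± 0.45 on the log2 scale (SE, n = 4 each, limma adjusted p = 0.0335), with probes between 0 and 1.57. It was above background on 3 of 4 contralateral arrays. miR-877 rose by 1.44 ± 0.30 (adjusted p = 0.0213 by limma), with probes between 0.70 and 1.23, and was above background on only 2 of 4 contralateral arrays. miR-680 rose by 1.16 ± 0.22 (limma adjusted p = 0.0172), or 2.24-fold, with probes between 1.02 and 1.09. For each of the 3 the change of the summed probes exceeded that of every single probe. With normexp background correction the log2 changes turned to -0.53, -0.61 and -0.62, none of them called, though relative to the median of all tested miRNAs they stayed at 0.092, 0.0092 and 0.0057.

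**Figure D2:**
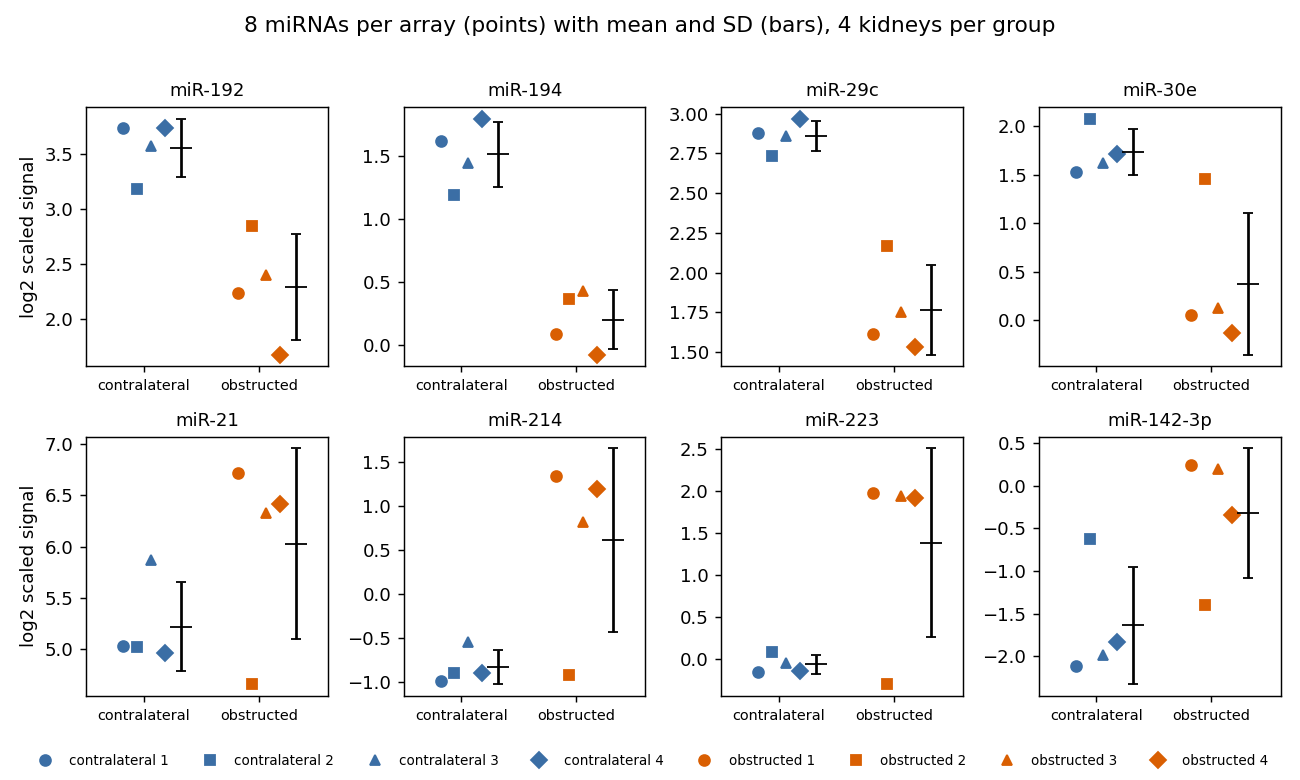
Log2 scaled signal of 8 miRNAs on each array (points) with the group mean and SD (bars), for 4 contralateral and 4 obstructed kidneys; each panel has its own axis, which does not start at 0. For miR-192, miR-194, miR-29c and miR-30e every obstructed array lies below every contralateral array, while for miR-21, miR-214, miR-223 and miR-142-3p obstructed kidneys 1, 3 and 4 lie above all contralateral arrays and obstructed kidney 2 does not.

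Of the miR-29 family, 3 of 5 tested members fell and none rose, and 4 fell when adjusted over the list alone. miR-29a changed by -0.49 ± 0.13 (SE, n = 4 each) on the log2 scale beside miR-29c and miR-29c*, and miR-29b by -0.73 ± 0.23 (limma adjusted p = 0.0721). The list had a median of -0.73 and stood below the other miRNAs (camera adjusted p = 0.0177), and adjusted p = 0.408 with an estimated correlation. Its median was 0.16 without scaling, and the camera call ended there (adjusted p = 0.0636), with the unscaled series matrix (0.0576) and with normexp (0.0641), within 0.000299 to 0.408 over all alternatives. The list stayed below the median of all tested miRNAs under each scaling and background setting, at -0.59 to -0.34 from it, although miR-29a turned to 0.25 above that median with normexp. Scaling by a constant per array could hardly have changed the side of that median on which the list lay. On the 7 arrays that remain when obstructed kidney 2 is dropped, 4 of 5 members fell.

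Of the miR-30 family, 2 of 10 tested members fell over all tested miRNAs, and 8 fell when adjusted over the list alone. The called members were miR-30e and miR-30a, with miR-30a at -0.84 ± 0.20 (SE, n = 4 each). miR-30c had a log2 change of -1.22 ± 0.37 (limma adjusted p = 0.0649) and miR-30d of -0.51 ± 0.19 (limma adjusted p = 0.101). The list stood below the other miRNAs (median -0.78, camera adjusted p = 0.0101), and adjusted p = 0.408 with an estimated correlation. The list median turned to 0.10 without scaling but stayed below the median of all tested miRNAs under each scaling and background setting, at -0.64 to -0.31 from it. Settings that scale by a constant per array could hardly have changed that. Obstructed kidney 2 was at -0.021 against the contralateral mean and the other obstructed kidneys between -1.10 and -0.96, and 8 of 10 members fell without it.

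In the kidney tubule group, miR-192 and miR-194 were the 2 of 5 tested members that fell, and 3 fell when adjusted over the list alone. miR-10b changed by -0.48 ± 0.15 (limma adjusted p = 0.0701) and miR-10a by 0.0043 ± 0.15 (limma adjusted p = 0.980; SE, n = 4 each). The list as a whole did not pass camera (adjusted p = 0.0916, and adjusted p = 0.408 with an estimated correlation) but passed fry (adjusted p = 0.00337). Its median of -0.48 turned to 0.40 without scaling, and relative to all tested miRNAs it turned to 0.0054 with normexp. All 4 obstructed kidneys lay between -0.84 and -0.54 of the contralateral mean, obstructed kidney 2 at -0.59.

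In the epithelial miR-200 family, which is known to repress Zeb1 and Zeb2, miR-200a and miR-429 were the 2 of 7 tested members that fell, by 0.72 (SE 0.16) and 0.60 (SE 0.14) on the log2 scale with n = 4 each; 5 fell when adjusted over the list alone. miR-200b had a log2 change of -0.59 ± 0.18 (limma adjusted p = 0.0649) and miR-200c of 0.15 ± 0.22 (limma adjusted p = 0.642). The list median was -0.56 (camera adjusted p = 0.0916, and adjusted p = 0.408 with an estimated correlation; fry adjusted p = 0.0418). That median was 0.32 without scaling, and relative to all tested miRNAs it turned to 0.11 with normexp, as did miR-429 on its own. With 3 obstructed arrays, kidney 2 left out, 5 of 7 members fell.

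No leukocyte marker, of miRNAs enriched in blood-derived immune cells, passed the test on all 8 arrays, with 0 of 6 tested members called over all tested miRNAs and 0 when adjusted over the list alone (limma, 4 at an unadjusted p under 0.05). miR-223 had a log2 change of 1.45 ± 0.50 (SE, n = 4 each, limma adjusted p = 0.0837), miR-142-3p of 1.31 ± 0.46, miR-342-3p of 1.46 ± 0.82 and miR-146a of 0.67 ± 0.30. As a list they stood above the other miRNAs (median 1.40, camera adjusted p = 0.00383), and adjusted p = 0.408 with an estimated correlation; fry gave an adjusted p of 0.0900. Obstructed kidneys 1, 3 and 4 lay 1.93 to 2.10 above the contralateral mean and obstructed kidney 2 lay at -0.46. Leaving out obstructed kidney 2, all 6 members rose, with miR-223 at 2.01 ± 0.10 (limma adjusted p = 5.81e-05; SE, n = 3 and 4), and the list had adjusted p = 0.0574 with an estimated correlation. Within slide row 1 the list median was 0.83 and within slide row 2 it was 1.95. Slide row 1 held obstructed kidney 1, at 2.10, and obstructed kidney 2, at -0.46, so its lower median reflects obstructed kidney 2. Over both rows the list median was 2.28 without scaling and 0.51 with normexp.

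Of the group of miR-21, miR-214 and miR-199, widely described in organ fibrosis, 0 of 6 tested members were called, and 0 when adjusted over the list alone (limma, 1 at an unadjusted p under 0.05). miR-21 had a log2 change of 0.81 ± 0.46 (SE, n = 4 each, limma adjusted p = 0.234), miR-214 of 1.44 ± 0.47 (limma adjusted p = 0.0774), miR-199a-5p of 1.16 ± 0.57 and miR-199a-3p of 1.05 ± 0.48. The list stood above the other miRNAs (median 1.10, camera adjusted p = 0.00474), and adjusted p = 0.408 with an estimated correlation; fry gave an adjusted p of 0.129. Obstructed kidney 2 lay at -0.54 against the contralateral mean and the other obstructed kidneys between 1.35 and 2.04. All 6 members rose when obstructed kidney 2 was left out, with miR-21 at 1.27 ± 0.25 (limma adjusted p = 0.00575; SE, n = 3 and 4) and miR-214 at 1.95 ± 0.17 (limma adjusted p = 0.000365).

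**Figure D3:**
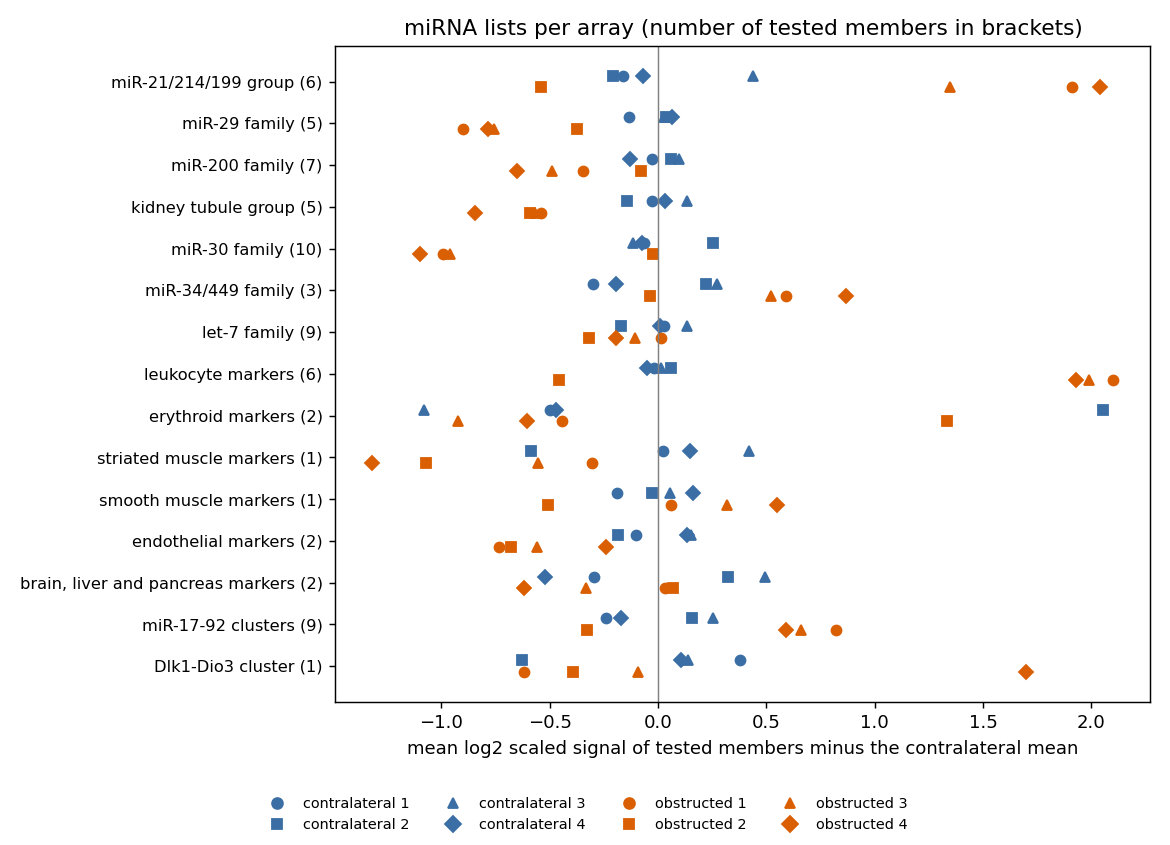
Mean log2 scaled signal of the tested members of each list on each array, minus the contralateral mean; blue points are contralateral and orange points obstructed kidneys, with the number of tested members in brackets. Obstructed kidneys 1, 3 and 4 lie 1.93 to 2.10 above the contralateral mean for leukocyte markers, where obstructed kidney 2 is at -0.46, while for the kidney tubule group all 4 obstructed kidneys lie between -0.84 and -0.54 under this scaling; that list's median turned to 0.40 without scaling and, relative to all tested miRNAs, to 0.0054 with normexp.

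The miR-17-92 clusters, proliferation-associated miRNAs of 3 paralogous clusters, had 0 of 9 tested members called, and 0 when adjusted over the list alone (limma, 0 at an unadjusted p under 0.05). Examples were miR-20a at 0.54 ± 0.30 and miR-92a at 0.37 ± 0.23 (SE, n = 4 each), with limma adjusted p-values of 0.234 and 0.274. miR-106b was at 0.30 ± 0.24 and miR-19b at 0.20 ± 0.26. The list stood above the other miRNAs (median 0.37, camera adjusted p = 0.00665), and adjusted p = 0.408 with an estimated correlation. Obstructed kidney 2 lay at -0.33 against the contralateral mean and the other obstructed kidneys between 0.59 and 0.82, and 7 of 9 members rose when it was left out.

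For the family of miR-34 and miR-449, p53-responsive and ciliated-cell miRNAs, 0 of 3 tested members were called, and 0 when adjusted over the list alone (limma, 2 at an unadjusted p under 0.05). miR-34c was at 0.93 ± 0.31 (SE, n = 4 each, limma adjusted p = 0.0788), miR-34b-5p at 0.72 ± 0.30 and miR-34a at -0.19 ± 0.20 (limma adjusted p = 0.531). The list median was 0.72 (camera adjusted p = 0.114) and turned to -0.53 with normexp, though it stayed 0.092 above the median of all tested miRNAs there. With obstructed kidney 2 left out, 2 of 3 members rose, miR-34c by 1.15 ± 0.27 (limma adjusted p = 0.0120; SE, n = 3 and 4) and miR-34b-5p by 0.96 ± 0.24 (limma adjusted p = 0.0152). Among the let-7 family, let-7g alone fell of 9 tested members, by 0.67 (SE 0.15, n = 4 each), and 1 fell when adjusted over the list alone; its change was 0.21 without scaling, and relative to the median of all tested miRNAs it was 0.072 with normexp. The abundant let-7a was at -0.34 ± 0.13, let-7f at -0.36 ± 0.14 and let-7c at -0.32 ± 0.13. The family did not move one way, with let-7e at 0.26 ± 0.18 and let-7i at 0.84 ± 0.35 (limma adjusted p = 0.123), both chosen after their values were seen. Once obstructed kidney 2 was left out, let-7i rose by 1.22 ± 0.13 (limma adjusted p = 0.000708; SE, n = 3 and 4) and 2 members fell. The list median of -0.29 (camera adjusted p = 0.212) turned to 0.60 without scaling and to 0.042 with quantile normalization, and relative to all tested miRNAs to 0.42 with normexp.

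Markers of other cells had too few tested members for a list test. The endothelial miR-126-5p fell by 0.81 (SE 0.18, n = 4 each, limma adjusted p = 0.0266), with 1 probe unchanged at the floor and a change of 0.074 without scaling, and miR-126-3p was at -0.30 ± 0.15 (limma adjusted p = 0.201); 1 of these 2 fell when adjusted over the list alone. The smooth muscle miRNA miR-143 was at 0.10 ± 0.23 and the striated muscle miRNA miR-1 at -0.81 ± 0.29 (limma adjusted p = 0.0906), which passed only when adjusted over the list alone, being its 1 tested member. Red blood cell miRNAs miR-451 and miR-486 were at -0.20 ± 0.77 and -0.11 ± 0.75, at 0.51 and 0.54 without contralateral kidney 2, and at -0.70 and -0.62 without obstructed kidney 2. Of the markers of brain, liver and pancreas, miR-9 was at -0.10 ± 0.24 and miR-9* at -0.32 ± 0.32. One member of the Dlk1-Dio3 cluster was tested, miR-494, at 0.15 ± 0.51; it was at -0.37 without obstructed kidney 4 and also below 0 without contralateral kidney 2. The hypoxia-responsive miR-210 was at 1.11 ± 0.81 (limma adjusted p = 0.337), and at 0.30 without obstructed kidney 4.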

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

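The tests of obstructed kidney 2, of array signal and of cell markers were chosen after the values were seen; the regrouping of arrays and the search for outlying arrays were planned before. The conditions for the wrong label and weaker response tests of obstructed kidney 2 were changed more than once after results were seen, and the verdict on the wrong label went from argued against to open and back, and that on the weaker response from open to argued against. A low array signal as the reason was also tested and then set aside; obstructed kidney 1, the next dimmest obstructed array, showed 107% of the leukocyte shift of obstructed kidneys 3 and 4.

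Regrouping the 8 arrays into 4 and 4 in all 35 ways gave at least 33 changed miRNAs in 2 of them, the real grouping included, and the highest other count was 45. For changes of at least 2-fold the real count was 15, 2 of the 35 groupings reached it, and the highest other was 35. The grouping with more calls exchanged contralateral kidney 3 with obstructed kidney 2, and the grouping by slide row gave 0. For lists past the threshold the real number was 5, and 5 of the 35 groupings gave as many, the highest other being 5. Chance was not excluded for any of these 3 counts. For the 7 arrays without obstructed kidney 2, 1 of 35 groupings, the real one, reached 113, and the highest other gave 12. The real grouping stood out there among the 7 arrays as given. Obstructed kidney 2 was left out on its values, because it lay nearest the contralateral arrays, and that choice favours the real grouping. This regrouping therefore cannot exclude chance.

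Of 144 groups of 4 arrays examined, 16 had an array far from the other 3, where chance gives about 1 in 20, or 7.2. Among these, obstructed kidney 2 was far from its group in its leukocyte markers, miR-30 family and 6 named miRNAs. Its leukocyte markers stood at -0.46 against the contralateral mean (others 1.93 to 2.10) and its miR-30 family at -0.021 (others -1.10 to -0.96). In log2 scaled signal it was at -0.30 for miR-223, -3.95 for miR-342-3p, -0.21 for miR-20a, -3.65 for miR-135a*, 1.46 for miR-30e and 1.61 for miR-30d.

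Obstructed kidney 2 lacked the leukocyte marker shift of the other obstructed kidneys. A swap with contralateral kidney 3 is argued against, since the leukocyte list of contralateral kidney 3 lay only 0.016 above the other contralateral kidneys, although its miR-21 was high. A contralateral kidney under a wrong label is argued against by the kidney tubule list of obstructed kidney 2, though not by every list. That list was at -0.59 against a contralateral range of -0.19 to 0.18 (SD 0.15). Relative to the median of each array it was below that range by over 1 SD under 7 of 8 scaling and background settings. These are not 7 separate checks, because a scaling constant cancels relative to that median. The list of obstructed kidney 2 was at -0.356 with the main, all-probe, median and no scaling alike, and at -0.298 with quantile normalization. With normexp no obstructed kidney left the contralateral range (-1.20 to 0.55), so that setting decides nothing. The miR-29 list of obstructed kidney 2 (-0.37) also lay below the contralateral arrays (-0.13 to 0.067). Its miR-200 (-0.081) and miR-30 (-0.021) lists lay among them (-0.13 to 0.098 and -0.12 to 0.25), and its leukocyte list showed no rise. A uniformly weaker response is argued against on the means of the tubule and leukocyte lists alone. Obstructed kidney 2 showed 90.7% of the tubule shift of the others and -22.8% of their leukocyte shift. Its other falling lists showed smaller parts. The other obstructed kidneys lay at -0.90 to -0.76 (miR-29), -0.65 to -0.35 (miR-200) and -1.10 to -0.96 (miR-30). Relative to the median of each array, the tubule list was at -0.36 in obstructed kidney 2 and at -0.74 to -0.35 in the others. The tubule part rests partly on miR-204, which did not fall in the others (-0.12 on all 8 arrays, 0.082 without this kidney). Its miR-194 (0.37) lay among the other obstructed kidneys (-0.077 to 0.42). Its miR-192 (2.85) and miR-10b (2.56) lay between the contralateral means (3.56 and 2.81) and the other obstructed kidneys (1.67 to 2.40 and 2.16 to 2.43). A kidney that responded in some miRNAs alone, or a sample from outside both groups, was not tested and stays open.

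More miRNAs were detected on obstructed arrays, and signal was higher on obstructed kidneys 1, 3 and 4, though the signal difference did not pass its test (exact permutation p = 0.0857) and obstructed kidney 2 lay among the contralateral arrays. A higher gain that acts on all spots alike is argued against, because the 2 bright control probes with names starting dmr differed by 0.040 (log2, SD 0.11) between the groups, against 0.88 for the 75th percentile. Better labelling or hybridization of the sample RNA cannot be told apart from a difference between the kidneys, since the 5 bright control probes with names starting hur or mr were 0.81 higher (log2, SD 0.86; 0.43 without obstructed kidney 4 and 1.23 without obstructed kidney 2) and neither what these probes measure nor the step at which the dmr probes were added is given. Negative controls were lower by 0.594 units on the obstructed arrays (a difference of -0.594). The software had already removed background and spatial trends, and these spots lay near 0 on every array (1.09 to 2.54 units). They therefore cannot decide on a higher non-specific signal. The amount or quality of the RNA and a higher miRNA content per unit of RNA after obstruction were not tested and stay open.

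The leukocyte list mean lay above the contralateral mean in obstructed kidneys 1, 3 and 4 but not in 2, and the kidney tubule list mean lay below it in all 4 under the scaling used. On all 8 arrays 0 of 6 leukocyte markers and 2 of 5 tubule miRNAs were called. Endothelial markers lay 2.52 below leukocyte markers in log2 (value -2.52, SD 0.34, obstructed kidneys 1, 3 and 4), and -1.94 (SD 1.18) over all 4 obstructed kidneys. In obstructed kidney 2, which lacked the leukocyte shift, the means were -0.68 (endothelial) and -0.46 (leukocyte). For kidneys 1, 3 and 4 the gap argues against a loss of tubule cells that raised endothelium and leukocytes alike, as far as miR-126 stands for endothelium. The endothelial markers are both strands of miR-126, so they cannot stand for all other cell types. An influx of leukocytes, or higher levels of these miRNAs in resident cells, may underlie the difference, and no test here separates them.

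Contralateral kidney 3 was far above its group for miR-21 (5.87, others 4.96 to 5.03) and for miR-199a-3p (1.55). Contralateral kidney 2 was far from its group for miR-451 (5.46, others 2.35 to 2.78), let-7c (4.64), miR-342-3p (-3.77) and the miR-30 family (0.25 against the contralateral mean). Obstructed kidney 4 was lowest for miR-429 (1.58) and for the kidney tubule group (-0.84).

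Probes outside the comparison also carried signal. Viral miRNA names above background numbered 3 on each contralateral array and on obstructed kidney 1, and 5, 4 and 7 on obstructed kidneys 2, 3 and 4. Some control probes were on average brighter on obstructed arrays than on any contralateral array, with means of 10237 for hur_1, 126406 for hur_2, 19038 for hur_4, 52517 for hur_6 and 3663 for mr_1 in scanner units. Obstructed kidneys 3 and 4 were the brightest arrays for each of these probes. hur_2 was at 48539 and 25673 on obstructed kidneys 1 and 2, and without obstructed kidney 4 its mean was 80705, below the 81875 of contralateral kidney 4. The means of hur_1, hur_4, hur_6 and mr_1 without obstructed kidney 4 (8352, 13179, 38936 and 2928) stayed above every contralateral array. Obstructed kidney 1 alone also exceeded every contralateral array for hur_6 (35579) and mr_1 (2324). What these control probes measure is not given in the sources used here.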

How the results depend on the processing

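All alternatives were planned except those that combine the loss of obstructed kidney 2 with another setting, which were chosen after seeing the data. Where no cause is given, the cause was not tested.

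The direction relative to the median of all tested miRNAs was kept under all 7 other scalings, background corrections and value sources by 27 of the 33 called miRNAs. Scaling by a constant per array, or leaving it out, shifts all miRNAs of an array alike apart from values at the floor. Such settings could hardly change this direction, and the series matrix holds the same spot signals. Quantile normalization, normexp and the summed gene signal were the settings that could change it. Of the 21 called miRNAs named, 12 kept their own sign in every alternative. Without scaling, and with the authors' unscaled series matrix, the median of all tested miRNAs moved by 0.88 and 0.87, which by construction turned small falls. The medians of the miR-29 and miR-30 families became 0.16 and 0.10 (unscaled matrix 0.16 and 0.10). miR-29a became 0.39 (0.38), miR-429 0.28 (0.28), miR-200a 0.16 (0.17), miR-30a 0.039 (0.049), let-7g 0.21 (0.21) and miR-126-5p 0.074 (0.13). The uncalled miR-200, kidney tubule and let-7 medians became 0.32, 0.40 and 0.60 (0.31, 0.39 and 0.59). With normexp, miR-135a*, miR-877 and miR-680 turned to -0.53, -0.61 and -0.62, the miR-29 median was -0.97 (adjusted p 0.0641, over all alternatives 0.000299 to 0.408) and the median of the miR-34 and miR-449 family -0.53. The let-7 median was 0.042 with quantile normalization. Lists above the other miRNAs kept their sign but changed in size. The leukocyte, miR-21, miR-214 and miR-199, and miR-17-92 medians were 2.28, 1.98 and 1.25 without scaling. With normexp they were 0.51, 0.82 and 0.12.

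Against 33 changed (15 at least 2-fold, 3 higher, 30 lower), scaling over all probes gave 0, 0, 0 and 0 (56 at an unadjusted p under 0.05), and normexp 0, 0, 0 and 0 (54). Median scaling gave 13 changed, 11 of them lower. Quantile normalization gave 3 (3, 1, 2), no scaling 3 (3 at least 2-fold, 0 lower), the unscaled matrix 3 (3, 0 lower) and summed gene signal 3 (3, 1 lower). Without a filter, with 611 miRNAs tested, 17 changed (3, 0, 17), and the filter on all 8 arrays left 1 higher. Array weights, from 0.114 (obstructed kidney 2) to 3.50 (contralateral kidney 4), gave 138 (60, 54, 84). Within slide row 1 the counts were 0, 0, 0 and 0 (1 at an unadjusted p under 0.05), within row 2 they were 69 (49, 20, 49), and with the row as a block 33. Leaving out 1 array gave 0 to 113 changed, 0 to 55 at least 2-fold, 0 to 46 higher and 0 to 67 lower, the upper ends without obstructed kidney 2.

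The replicate number as a block gave 0 changed, 0 at least 2-fold, 0 higher and 0 lower (67 at an unadjusted p under 0.05, limma). Kidneys of the same number did not deviate together in all pairs (r of -0.35, 0.22, 0.62 and 0.01). Of the obstructed kidneys only kidney 3 correlated best with its own number, and of the contralateral kidneys only kidneys 2 and 3 did. This check cannot exclude pairs, because obstructed kidney 2 shifts the mean of its group. Contralateral kidney 3 gave r of 0.57, -0.60 and 0.62 with obstructed kidneys 1, 2 and 3. miR-451 was high in both kidneys numbered 2 (5.46 and 4.59). Pairing stays undecided, and the fit without a block was kept because the labels state no pairs.

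List calls ended with an estimated correlation at adjusted p 0.408 for the group of miR-21, miR-214 and miR-199 (median 1.10), leukocyte markers (1.40), the miR-17-92 clusters (0.37) and the miR-29 (-0.73) and miR-30 (-0.78) families. With fry they ended for the first 3 and miR-30 (adjusted p 0.129, 0.0900, 0.200 and 0.0546), while the miR-200 family (-0.56) and kidney tubule group (-0.48) passed (0.0418 and 0.00337). With miRNAs above background on at least 1 array the miR-17-92 clusters gave 0.0575 (median 0.37, over all alternatives 0.000266 to 0.408). Without a filter, the miR-200, kidney tubule and let-7 (-0.29) lists passed at 0.0208, 0.0208 and 0.00112 (over all alternatives up to 0.488, 0.408 and 0.933). The miR-200 and kidney tubule lists also passed without contralateral kidney 4 (adjusted p 0.0490 each, medians -0.54 and -0.54). Leaving out 1 array gave list medians of 1.14 to 1.99 (leukocyte), 0.82 to 1.67 (miR-21, miR-214 and miR-199), 0.26 to 0.65 (miR-17-92), -0.91 to -0.60 (miR-29), -1.01 to -0.68 (miR-30), -0.73 to -0.48 (miR-200), -0.55 to -0.41 (kidney tubule), 0.51 to 0.96 (miR-34 and miR-449) and -0.35 to -0.26 (let-7). It gave 0.63 to 1.17 for the log2 difference in array signal.

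Without obstructed kidney 2, 113 became 72 with scaling over all probes and 33 with normexp, and 89 to 112 with a further array left out. Signal over background limited dim miRNAs such as miR-877, which were undetected on some contralateral arrays.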

Other observations

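The features described here were chosen after their values were seen.

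Beyond the named miRNAs, the largest rises without obstructed kidney 2 were those of miR-146b and miR-132, members of the leukocyte list and of the group of miR-21, miR-214 and miR-199. miR-146b rose by 3.11 ± 0.22 on the log2 scale (SE, n = 3 and 4, limma adjusted p = 0.000243), or 8.62-fold, and miR-132 by 2.54 ± 0.58 (limma adjusted p = 0.0107). miR-155, known from activated immune cells, rose by 1.98 ± 0.21 and miR-31 by 1.82 ± 0.36. On all 8 arrays none of these was called, with miR-146b at 2.10 ± 0.90 (limma adjusted p = 0.130; SE, n = 4 each).

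miRNAs named miR-466 and miR-467 had 10 tested members of 24 on the array. On all 8 arrays 0 were called (limma, smallest adjusted p 0.0959, for miR-467b), with 8 of 10 below 0 and a median log2 change of -0.87. Without obstructed kidney 2, 7 fell and 1 rose, the latter being miR-467b at 1.17 ± 0.26 (limma adjusted p = 0.00970; SE, n = 3 and 4). miR-467f was at -1.58 ± 0.32 in that fit, while obstructed kidney 2 stood at 0.56 in log2 scaled signal, above every contralateral array.

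Both kidneys with the number 2 had high red blood cell miRNAs. miR-451 was at 5.46 in contralateral kidney 2 and 4.59 in obstructed kidney 2, against 2.34 to 2.90 in the other 6 kidneys. miR-486 was at -1.30 and -1.87, against -4.46 to -3.61. miR-210 was at 0.42 in obstructed kidney 4 and between -3.85 and -1.99 in the other 7.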
